A study of Mus musculus with 12 samples.

How the data were processed

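Gene expression was measured on 12 one-colour Affymetrix mouse arrays, 3 per group. The groups were hindlimb muscle of uninduced mice (CTL), tumours at day 0 of doxycycline removal (TUM), and tumours 3 days (OFF3) and 6 days (OFF6) after its removal. Total RNA was extracted with Trizol and an RNeasy kit and turned into biotin-marked cRNA, per the labels. The deposited values are probe set intensity on a linear scale, computed by the authors with RMA, a method that corrects background, normalises arrays and summarises probes. Its version was not given in the sources used here. The scanner files were not used here.

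The file held 34760 probe sets. Of these, 21640 carried 1 gene symbol, 1321 carried several and 11799 carried none, and only the first kind was used. Log2 of the intensity was taken first. Where a gene had several probe sets (954 genes), the one with the highest mean was kept, which left 19937 genes. Median intensity per array ran from 86.74 to 93.05, with no filter on low values. Arrays give no count per gene, so the number of arrays limits the precision. The median standard error of a log2 difference was 0.086 with 12.2 degrees of freedom.

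One linear model with a mean per group was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3. Tables were read with version 1.17.8 of the data.table package, and statmod 1.5.0 served the fit with a replicate block. Plots were drawn in Python 3.11.15 with matplotlib 3.10.9. The comparisons were OFF3, OFF6 and CTL each minus TUM, OFF6 minus OFF3, and OFF6 minus CTL. Tests were two-sided, p-values were adjusted by Benjamini and Hochberg within each comparison, and an adjusted p under 0.05 was called a change. The labels do not say that the replicates were separate animals, so the p-values measure only the spread between these samples.

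Before the data were examined, 22 gene lists were written from textbook knowledge: YAP and TAZ target genes, Hippo pathway components, satellite cell and myoblast genes, early and embryonic muscle genes, adult contractile and fibre genes, cell cycle genes, p53 and apoptosis genes, oncofetal and imprinted genes, ribosome biogenesis and Myc genes, oxidative phosphorylation and citrate cycle genes, hypoxia and glycolysis genes, interferon response genes, sex-linked genes, and markers of macrophages, neutrophils, lymphocytes and NK cells, endothelium, fibroblasts and matrix, pericytes and smooth muscle, adipocytes, Schwann cells and erythroid cells. Of their 380 genes, 352 were measured. Each list was tested against all other genes with limma camera at a preset correlation of 0.01, and adjusted over the 110 tests of 22 lists and 5 comparisons. Camera with an estimated correlation and fry, which asks whether a list's genes move one way on balance, were run beside it. With the preset correlation 52 of the 110 tests passed, with an estimated correlation 0, and with fry 79. Every camera call of a list therefore rests on the preset correlation. Fry, which uses no such correlation and asks another question, lost 1 of those 52 calls.

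Genes to be named were also chosen by a rule set before the data were examined. Always named were Yap1, Ccn2 (Ctgf), Ccn1 (Cyr61), Ankrd1, Pax7, Myf5, Myod1, Myog, Myh3, Myh4, Ckm, Mki67 and Ccnd1. For each comparison with TUM, the rule added the 6 largest rises and the 6 largest falls among called genes whose arrays lay wholly on one side of TUM, leaving out predicted genes. It added 3 each way for OFF6 minus OFF3, and for each list the 2 to 4 members with the largest difference plus the largest called member against the majority. A difference is given in log2 units ± its standard error, with 3 arrays per group. Genes of the osteoclast and granzyme sets, and the X-linked partners of Y-linked genes, were chosen after values had been seen. Alternatives that leave out OFF6 replicate 2 from list tests and from counts of shared genes were also added then. Brightest genes are those above the upper quartile of mean level.

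The alternatives chosen at the same time were other ways to treat several probe sets per gene, a filter on low values, 3 other scalings of the arrays, a trended and robust variance, array weights, a replicate block, models of only the 6 arrays compared, a stricter threshold, a minimum fold of 2, a test of all probe sets, and leaving out each array in turn. OFF3, OFF6 and CTL share the TUM arrays. The correlation and covariance of their changes were therefore set beside 20 simulations of unchanged groups that shared simulated TUM arrays. The procedure was tested on simulated data for OFF3 minus TUM, with 67, 67 and 66 of 19937 genes changed 1.5-, 2- and 4-fold. It recovered 80.6%, 95.5% and 100% of these, 0 with the wrong sign, and 7.5% of calls were unchanged genes. A list of 25 genes shifted by 0.5 had p = 6.24e-77 with camera's preset correlation and 4.39e-07 with an estimated one. With either, 1 of 100 unshifted lists had p under 0.05. Correlated genes were not simulated, so the preset stays untested for them.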

Results

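The study asks what YAP1, the growth-promoting effector of the Hippo pathway, does in rhabdomyosarcoma, a tumour with features of skeletal muscle. Mice carried a mutant human YAP1 that doxycycline switches on in cells with a Myf5 history (Myf5Cre). Donor mice received doxycycline for 4 weeks, and interstitial cells of their hindlimb muscle were transplanted into the gastrocnemius of doxycycline-treated NOD/SCID hosts. Tumours were taken with doxycycline on (TUM, day 0) and 3 or 6 days after its removal (OFF3, OFF6), and hindlimb muscle of uninduced mice of the same genotype served as control (CTL). Each group had 3 arrays, with 19937 genes tested per comparison.

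The first principal component held 80.1% of the variance and set the 3 CTL arrays (-100.9 to -96.8) apart from the tumour arrays (19.1 to 50.1). The second, with 11.6%, set the TUM arrays (31.9 to 34.5) apart from the OFF3 and OFF6 arrays (-24.7 to -15.5). The third, with 4.2%, set OFF6 replicates 1 and 3 (26.3 and 26) apart from the OFF3 arrays (-16.9 to -13.6), and OFF6 replicate 2 lay at -6.4. Across genes, the mean correlation of OFF6 replicate 2 was 0.991 with its own group and 0.995 with OFF3. Values without this array are therefore given for the day 6 lists whose counts change or whose medians move by over 1.5 times. Genes are not independent replicates, so these correlations describe arrays only.

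By 3 days after doxycycline removal, cell division genes fell and muscle genes rose in the tumours. Mki67 (-1.67 ± 0.12), a proliferation marker, fell from a log2 intensity of 10.16 ± 0.05 to 8.50 ± 0.17 (SD, n = 3), 3.17-fold. Ccn1, a direct YAP target encoding a matrix-associated signalling protein, fell from 11.34 ± 0.01 to 9.86 ± 0.06, 2.78-fold. Perinatal myosin heavy chain Myh8 rose from 8.07 ± 0.10 to 10.52 ± 0.12, 5.49-fold, and embryonic myosin Myh3 from 9.67 ± 0.02 to 11.25 ± 0.07, 2.99-fold. The largest adjusted p of these 4 was 9.28e-07, and in each the OFF3 arrays lay wholly outside the range of TUM.

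Of 31 cell cycle genes, 30 fell and 0 rose, the same number adjusted over the list alone. Bub1 (-2.84 ± 0.26), Plk1 (-2.36 ± 0.21), Cenpe (-2.28 ± 0.15) and Top2a (-2.24 ± 0.22), which act in chromosome segregation and DNA untangling, fell most, and Ccnd1 (-1.13 ± 0.09), a G1 cyclin, fell too. The list's median was -1.73 with adjusted p = 6.24e-28, and adjusted p = 0.158 with an estimated correlation. Of 16 ribosome biogenesis and Myc genes, 15 fell and 0 rose, also 15 adjusted over the list alone. The median was -0.58 (adjusted p = 7.76e-11; adjusted p = 0.179 with an estimated correlation). Myc (-1.48 ± 0.12), Rrp9 (-1.22 ± 0.11) and Nop58 (-1.01 ± 0.09) fell most, Myc being a growth-promoting transcription factor and the others rRNA processing factors.

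Among 24 YAP and TAZ target genes, 14 fell, 4 rose and 6 did not pass; adjusted over the list alone, 15 fell and 5 rose. Ajuba (-1.91 ± 0.12), Amotl2 (-1.85 ± 0.08), Ccn1 (-1.48 ± 0.07) and Ankrd1 (-1.33 ± 0.16) fell most, while F3 (1.22 ± 0.19), tissue factor, rose. Ccn2, another classic YAP target, differed by 0.09 ± 0.07 (adjusted p = 0.459) and passed only with array weights. The median was -0.38 with adjusted p = 0.000285, and adjusted p = 0.158 with an estimated correlation. The Yap1 signal fell by 0.29 on the log2 scale (± 0.07, adjusted p = 0.00923); the transgene is human, and how far this mouse probe set (10590808) reads it is not known.

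Of 19 Hippo pathway components, 2 rose and 6 fell (2 and 8 adjusted over the list alone), with median -0.18, adjusted p = 0.0265, and adjusted p = 0.262 with an estimated correlation. The atypical cadherin Fat4 (1.19 ± 0.12) rose, and Wwc1 (-1.04 ± 0.08), Vgll3 (-0.87 ± 0.08) and Frmd6 (-0.72 ± 0.10) fell. This list call was lost with quantile normalisation (adjusted p = 0.146), among genes above the median level (0.331), and without OFF3 replicate 3 (median -0.17, adjusted p = 0.0591), a range of 0.000648 to 0.331 over all alternatives.

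Of 31 adult contractile and fibre genes, 29 rose and 0 fell, the same adjusted over the list alone. The calcium buffer Pvalb (1.95 ± 0.40), the AMP deaminase Ampd1 (1.91 ± 0.16), the Z-disc gene Myoz1 (1.84 ± 0.11) and the glycolytic Pgam2 (1.83 ± 0.14) rose most, and the fast myosin Myh4 (1.18 ± 0.12) and creatine kinase Ckm (1.01 ± 0.10) rose too. The median was 1.12, adjusted p = 1.09e-21, and adjusted p = 0.193 with an estimated correlation. Of 19 early and embryonic muscle genes, 15 rose and 1 fell, the same adjusted over the list alone. The median was 0.80 (adjusted p = 2.55e-08; adjusted p = 0.262 with an estimated correlation). Beside Myh8 and Myh3, the slow troponin Tnni1 (1.55 ± 0.11) and cardiac actin Actc1 (1.40 ± 0.10) rose most, and Chrnb1 (-0.41 ± 0.10), an acetylcholine receptor subunit, fell. The myogenic factor Myog (1.01 ± 0.14) rose.

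Of 19 satellite cell and myoblast genes, 7 rose and 6 fell (8 and 6 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.933). Its median (0.01) and mean (0.06) were above 0 while the test pointed down. The phagocytic receptor Megf10 (1.28 ± 0.20) and the chemokine receptor Cxcr4 (1.08 ± 0.16) rose, and Sdc4 (-1.05 ± 0.08) and Met (-1.02 ± 0.10) fell. Myf5, an early myogenic factor, fell (-0.78 ± 0.08), and Pax7, the satellite cell factor, differed by -0.05 ± 0.08 (adjusted p = 0.77). Myod1 differed by 0.50 ± 0.17 with adjusted p = 0.0457. The Myod1 call was lost when any 1 of the 3 TUM or 3 OFF3 arrays was left out (adjusted p from 0.082 to 0.122), with a replicate block (0.0615) and with arrays centred on their median (0.0731).

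Stromal markers rose as well. Of 18 fibroblast and matrix genes 16 rose and 0 fell, the same adjusted over the list alone, led by Lum (2.26 ± 0.26), Fap (1.93 ± 0.18), Tnc (1.66 ± 0.15) and Col6a3 (1.58 ± 0.09). The median was 0.82 (adjusted p = 6.74e-11; adjusted p = 0.179 with an estimated correlation). Of 15 endothelial markers 14 rose and 0 fell (15 and 0 adjusted over the list alone), led by Vwf (1.18 ± 0.13), Tek (0.88 ± 0.13) and Eng (0.76 ± 0.08). The median was 0.52 (adjusted p = 3.88e-09; adjusted p = 0.158 with an estimated correlation). Of 11 pericyte and smooth muscle markers 8 rose and 1 fell (9 and 1 adjusted over the list alone), with Abcc9 (1.41 ± 0.11), Rgs5 (1.25 ± 0.13) and Tagln (0.78 ± 0.14) up and Cspg4 (-0.52 ± 0.11) down. The median was 0.44 (adjusted p = 0.00099; adjusted p = 0.158 with an estimated correlation). Among 20 macrophage markers 5 rose and 2 fell (5 and 2 adjusted over the list alone), and the list did not pass (median 0.29, adjusted p = 0.0687). The scavenger receptor Msr1 (-1.13 ± 0.10) fell while Aif1 (0.77 ± 0.16) rose. The macrophage list passed with quantile normalisation (0.0376), arrays centred on their median (0.035), array weights (0.0375) and only the 6 arrays (0.00384), a range of 0.00384 to 0.707 over all alternatives.

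Of 20 oxidative phosphorylation and citrate cycle genes 7 rose and 1 fell (8 and 1 adjusted over the list alone). Muscle-type cytochrome oxidase subunits Cox7a1 (1.41 ± 0.07), Cox8b (1.37 ± 0.09) and Cox6a2 (1.03 ± 0.13) and the mitochondrial regulator Ppargc1a (1.08 ± 0.15) rose most. The median was 0.13 (adjusted p = 0.0119; adjusted p = 0.346 with an estimated correlation). Of 14 hypoxia and glycolysis genes 2 rose and 6 fell (2 and 8 adjusted over the list alone), with the glucose transporter Slc2a1 (-0.98 ± 0.12) and Vegfa (-0.74 ± 0.08) down and Pfkfb3 (0.84 ± 0.13) up. The median was -0.27 (adjusted p = 0.0151; adjusted p = 0.256 with an estimated correlation). The call of the first list was lost with array weights (adjusted p = 0.134) and in a model of only the 6 arrays (0.0525), and that of the second among genes above the median level (0.293). Adjusted p ran from 0.000777 to 0.346 over all alternatives for the first and 0.000258 to 0.293 over all alternatives for the second.

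The remaining lists did not pass at day 3. Rises and falls were 7 and 1 of 14 p53 and apoptosis genes (median 0.20, adjusted p = 0.0664), 6 and 3 of 13 oncofetal and imprinted genes (median 0.26, adjusted p = 0.473), 5 and 1 of 17 interferon response genes (median 0.11, adjusted p = 0.202), and 5 and 1 of 15 lymphocyte and NK markers (median 0.13, adjusted p = 0.0968). They were 1 and 1 of 12 neutrophil markers (median 0.08, adjusted p = 0.461), 3 and 0 of 11 adipocyte markers (median 0.15, adjusted p = 0.0923), 0 and 0 of 7 Schwann cell markers (median 0.11, adjusted p = 0.401), 0 and 0 of 2 erythroid markers (median 0.06, adjusted p = 0.863), and 3 and 0 of 4 sex-linked genes (median 0.64, adjusted p = 0.0923). Counts adjusted over the list alone differed only for the oncofetal list, with 4 falls. The neutrophil list's mean (-0.07) lay below 0 and its median above. In the oncofetal list, the RNA-binding Igf2bp1 (-2.20 ± 0.08) and the chromatin protein Hmga2 (-1.16 ± 0.06) fell and the imprinted Plagl1 (1.39 ± 0.20) and Grb10 (1.31 ± 0.11) rose. The p53 list passed without OFF3 replicate 3 (median 0.19, adjusted p = 0.0441) or TUM replicate 3 (0.17, 0.0467) and with arrays centred on their median, a range of 0.000168 to 0.215 over all alternatives. In a model of only the 6 arrays the lymphocyte and sex-linked lists passed, the lymphocyte list also with array weights. Fry also called the p53, lymphocyte, adipocyte and sex-linked lists.

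The 6 largest rises were Mylk4 (2.97 ± 0.14), Snora44 (2.73 ± 0.50), Pamr1 (2.72 ± 0.10), Sfrp4 (2.56 ± 0.45), Dpt (2.52 ± 0.21) and Itih5 (2.47 ± 0.23); Mylk4 is a muscle kinase, and Sfrp4, Dpt and Itih5 encode secreted or matrix proteins. The 6 largest falls were Clca3a1 (-3.46 ± 0.13), Atp6v0d2 (-3.21 ± 0.15), Oscar (-3.14 ± 0.10), Sprr1a (-3.13 ± 0.20), Mmp9 (-2.88 ± 0.23) and Clca3a2 (-2.86 ± 0.23). Atp6v0d2, Oscar and the protease Mmp9 are known from osteoclasts. Over all genes 5868 passed, 2671 higher and 3197 lower at day 3, and 760 of them by at least 2-fold (365 and 395). Array weights called 11175 genes and turned the split (6181 higher and 4994 lower), and arrays centred on their median gave 2317 and 3532. The OFF3 and TUM arrays did not overlap in 8939 genes (44.8%), where chance gives 10%.

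**Figure D1:**
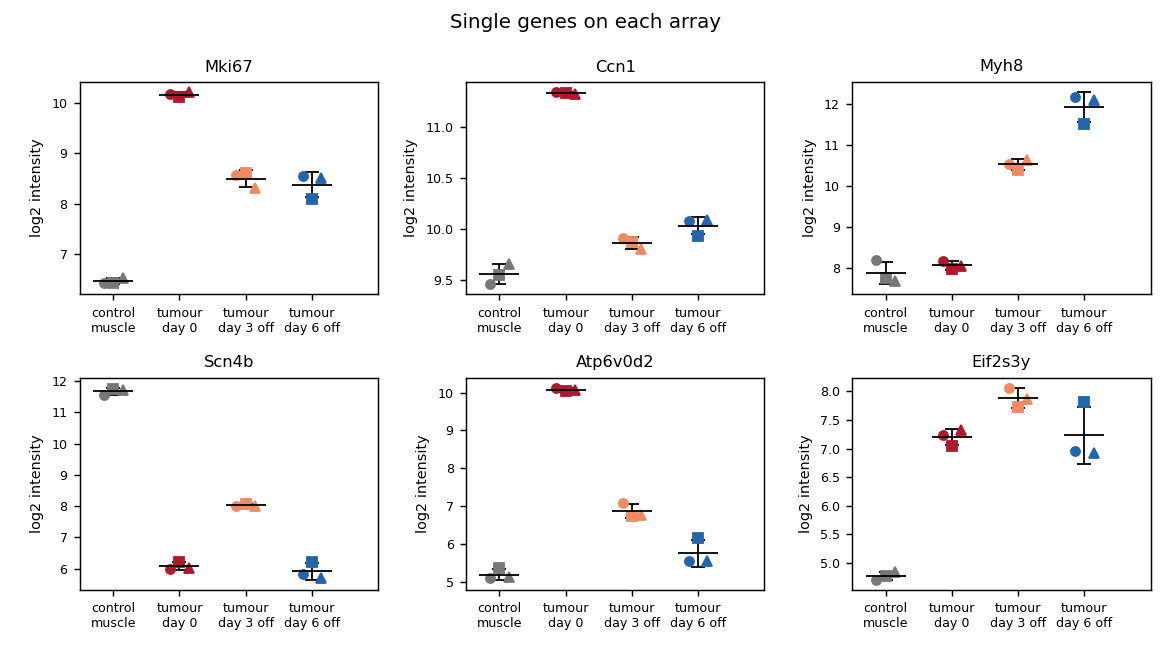
Log2 intensity of 6 genes on each array (circle, square and triangle are replicates 1, 2 and 3) in control muscle and in tumours at day 0, 3 and 6, with the mean as a bar and the SD as whiskers (n = 3). Myh8 averaged 8.07 at day 0 and 11.92 at day 6, while Scn4b averaged 6.08, 8.03 and 5.91 at days 0, 3 and 6.

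By 6 days after doxycycline removal, early muscle genes stood far above their day 0 level. Myh8 rose 14.5-fold, from a log2 intensity of 8.07 ± 0.10 to 11.92 ± 0.37 (SD, n = 3), the largest rise of all genes under the naming rule, and Myh3 rose 4.87-fold to 11.96 ± 0.27. Mki67 fell 3.45-fold to 8.38 ± 0.26, and Ccn1 2.47-fold to 10.03 ± 0.09. Atp6v0d2, a proton pump subunit of osteoclasts, fell 19.9-fold, from 10.07 ± 0.05 to 5.76 ± 0.36. The largest adjusted p of these 5 was 2.41e-07, and in each the OFF6 arrays lay wholly outside the range of TUM.

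Of 19 early and embryonic muscle genes, 17 rose and 0 fell, the same adjusted over the list alone, and without OFF6 replicate 2 the rises numbered 18. Slow-fibre troponins Tnni1 (2.36 ± 0.11) and Tnnt1 (2.13 ± 0.13) rose most after Myh8, next to Myh3 (2.28 ± 0.12). The median was 1.43 (adjusted p = 7.11e-13; adjusted p = 0.197 with an estimated correlation). Of 31 adult contractile and fibre genes 28 rose and 0 fell, with 29 rises adjusted over the list alone and 29 rises and 1 fall without OFF6 replicate 2. The calcium channel Cacna1s (2.33 ± 0.16), Pgam2 (2.02 ± 0.14) and the Z-disc genes Tcap (1.94 ± 0.09) and Ldb3 (1.86 ± 0.13) rose most, and Myh4 (1.03 ± 0.12) and Ckm (0.57 ± 0.10) rose too. The median was 1.19 (adjusted p = 4.39e-20; adjusted p = 0.197 with an estimated correlation). The myogenic factors Myod1 (1.15 ± 0.17) and Myog (1.21 ± 0.14) rose and Myf5 (-0.88 ± 0.08) fell.

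Of 31 cell cycle genes 31 fell, the same adjusted over the list alone and without OFF6 replicate 2, with Bub1 (-2.65 ± 0.26), Top2a (-2.22 ± 0.22), Cenpe (-2.14 ± 0.15) and Kif11 (-2.07 ± 0.17) falling most and Ccnd1 (-1.18 ± 0.09) falling as well. The median was -1.66 (adjusted p = 3.82e-27; adjusted p = 0.158 with an estimated correlation). Of 16 ribosome biogenesis and Myc genes 12 fell and 0 rose, the same adjusted over the list alone, led by Myc (-1.29 ± 0.12), Cad (-0.95 ± 0.08) and Nop58 (-0.87 ± 0.09). The median was -0.52 (adjusted p = 2.55e-08; adjusted p = 0.197 with an estimated correlation). Of 20 oxidative phosphorylation and citrate cycle genes 12 rose and 0 fell, the same adjusted over the list alone, including Cox7a1 (1.45 ± 0.07) and Cox8b (1.37 ± 0.09). The median was 0.25 (adjusted p = 1.98e-05; adjusted p = 0.21 with an estimated correlation). The ribosome list had 12 falls and 1 rise without OFF6 replicate 2, and the mitochondrial list 15 rises.

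Among 24 YAP and TAZ target genes, 12 fell and 6 rose, also without OFF6 replicate 2, and 14 and 6 adjusted over the list alone. Amotl2 (-2.08 ± 0.08), Ajuba (-1.76 ± 0.12) and Ccn1 (-1.31 ± 0.07) fell most, while the stress gene Gadd45a (1.62 ± 0.12) and Ccn2 (0.41 ± 0.07) rose. The median was -0.41 (adjusted p = 0.000715; adjusted p = 0.158 with an estimated correlation). Ankrd1 differed by -0.41 ± 0.16 (adjusted p = 0.0797), and passed without OFF6 replicate 1 (-0.54, adjusted p = 0.0356) or replicate 3 (-0.53, 0.0428); its difference was -0.16 without OFF6 replicate 2 (0.0319 to 0.209 over all alternatives). Yap1 fell (-0.25 ± 0.07, adjusted p = 0.0203), a call lost without TUM replicate 2 (-0.24, 0.0631), TUM replicate 3 (-0.25, 0.0614) or OFF6 replicate 2 (-0.19, 0.0609), a range of 0.00255 to 0.0631 over all alternatives. Of 19 Hippo pathway components 4 rose and 8 fell, the same adjusted over the list alone, with the YAP-binding factor Tead4 (1.43 ± 0.21) up and Frmd6 (-1.04 ± 0.10) down, and the list did not pass (median -0.13, adjusted p = 0.0927). Without OFF6 replicate 2 it had 5 rises and 7 falls, with median -0.06.

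Of 18 fibroblast and matrix genes 12 rose and 1 fell, the same adjusted over the list alone, led by Tnc (1.84 ± 0.15), Lum (1.76 ± 0.26), Fap (1.46 ± 0.18) and Dcn (1.22 ± 0.15), and without OFF6 replicate 2 the counts were 11 and 2. The median was 0.56 (adjusted p = 0.000319; adjusted p = 0.303 with an estimated correlation). Of 15 endothelial markers 10 rose and 0 fell, the same adjusted over the list alone and 9 rises without OFF6 replicate 2, led by Vwf (0.85 ± 0.13) and Tek (0.75 ± 0.13). The median was 0.29 (adjusted p = 0.00138; adjusted p = 0.262 with an estimated correlation). Of 11 pericyte and smooth muscle markers 6 rose and 1 fell (7 and 2 adjusted over the list alone), with Abcc9 (2.00 ± 0.11) highest, and the list missed the threshold (median 0.48, adjusted p = 0.0521). It passed without OFF6 replicate 3 (0.0365), TUM replicate 2 (0.0404) or TUM replicate 3 (0.0471), under the 3 other scalings, with a trended and robust variance and with a replicate block, a range of 2.65e-06 to 0.198 over all alternatives. Without OFF6 replicate 2 it had 7 rises and 2 falls and did not pass.

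Of 17 interferon response genes 11 rose and 0 fell, the same adjusted over the list alone and without OFF6 replicate 2, led by Oas2 (0.69 ± 0.10) and Ifit2 (0.67 ± 0.12), which encode antiviral proteins. The median was 0.32 (adjusted p = 0.00157; adjusted p = 0.262 with an estimated correlation). Among 20 macrophage markers 1 rose and 3 fell (0 and 3 adjusted over the list alone), and the list did not pass (median -0.03, adjusted p = 0.287). Leaving out OFF6 replicate 2, 8 of them fell and 0 rose, the median was -0.15 and the list passed (adjusted p = 0.00154; 0.00154 to 0.83 over all alternatives), as it did with array weights. Msr1 (-1.37 ± 0.10) fell with all arrays in the model.

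The remaining lists did not pass at day 6. Rises and falls were 4 and 9 of 19 satellite cell and myoblast genes (median -0.20, adjusted p = 0.142), 6 and 2 of 14 p53 and apoptosis genes (median 0.22, adjusted p = 0.142), 5 and 3 of 13 oncofetal and imprinted genes (median 0.19, adjusted p = 0.734), 3 and 6 of 14 hypoxia and glycolysis genes (median -0.09, adjusted p = 0.202), and 1 and 1 of 12 neutrophil markers (median 0.13, adjusted p = 0.401). They were 3 and 1 of 15 lymphocyte and NK markers (median 0.14, adjusted p = 0.157), 2 and 1 of 11 adipocyte markers (median 0.18, adjusted p = 0.24), 0 and 0 of 7 Schwann cell markers (median 0.12, adjusted p = 0.72), 0 and 0 of 2 erythroid markers (median 0.15, adjusted p = 0.555), and 0 and 0 of 4 sex-linked genes (median 0.04, adjusted p = 0.892). Adjusted over the list alone, counts were 6 and 9 for satellite cell, 6 and 3 for p53, 6 and 3 for oncofetal and 4 and 6 for hypoxia genes, and otherwise the same. The neutrophil list's mean was -0.12, with median and test above 0. The sex-linked list's test pointed down, with mean 0.00 and median above 0. Megf10 (2.46 ± 0.20) rose and the growth factor receptor Met (-1.32 ± 0.10) fell in the satellite cell list, the fetal growth factor Igf2 (1.51 ± 0.08) rose and Igf2bp1 (-2.24 ± 0.08) and Hmga2 (-1.60 ± 0.06) fell in the oncofetal list, and Eda2r (1.40 ± 0.12) and Pmaip1 (1.09 ± 0.13) rose in the p53 list. Pax7 fell (-0.31 ± 0.08, adjusted p = 0.0125), a call lost without OFF6 replicate 3 (-0.27, adjusted p = 0.0547; 0.000195 to 0.0547 over all alternatives). With OFF6 replicate 2 left out, rises and falls were 6 and 8 for satellite cell genes (median -0.03), 7 and 1 for p53 genes, 6 and 4 for oncofetal genes, 4 and 6 for hypoxia genes, 2 and 2 for adipocyte genes (median 0.12), 0 and 1 for Schwann cell genes (median 0.06) and 0 and 0 for sex-linked genes (median -0.26), with the other counts the same. Fry also called the Hippo, satellite cell, p53, hypoxia, lymphocyte and pericyte lists. It called the oncofetal list downwards.

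The largest rises after Myh8 were Armh4 (3.59 ± 0.28), Tecrl (3.50 ± 0.20), Tcp11x2 (3.42 ± 0.27), Zdbf2 (3.39 ± 0.33) and Tmod1 (3.11 ± 0.19); Tmod1 caps the thin filaments of muscle. The largest falls were Atp6v0d2 (-4.32 ± 0.15), Gzmf (-4.24 ± 0.31), Gzmd (-3.97 ± 0.25), Clca3a1 (-3.86 ± 0.13), Gzmg (-3.66 ± 0.25) and Mmp9 (-3.64 ± 0.23); the Gzm genes encode granzymes, proteases of cytotoxic lymphocytes, and related members can share probes. Over all genes 6279 passed, 2962 higher and 3317 lower, and 892 by at least 2-fold (465 and 427). With array weights 10545 genes passed and the split turned (5658 higher and 4887 lower), and arrays centred on their median gave 2398 and 3782. Without OFF6 replicate 2 the counts were 3222 and 3664, and 5713 genes were called in the same direction both ways. OFF6 and TUM did not overlap in 9668 genes (48.5%), where chance gives 10%.

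Control muscle differed from day 0 tumours in most genes. Contractile, mitochondrial and fat genes were higher in muscle, and cell cycle, interferon and macrophage genes were lower. Myokine genes Ostn (5.94 ± 0.07) and Mstn (5.67 ± 0.18), the muscle kinase Mylk4 (5.86 ± 0.14) and the sodium channel subunit Scn4b (5.60 ± 0.12) were among the 6 genes highest in muscle, with Plcd4 (5.39 ± 0.18) and Mlf1 (5.29 ± 0.21). The 6 lowest were Gzmd (-6.15 ± 0.25), Brinp3 (-5.74 ± 0.14), Glipr1 (-5.39 ± 0.16), Steap2 (-5.20 ± 0.16), Clca3a1 (-5.11 ± 0.13) and Gzmf (-4.92 ± 0.31). The largest adjusted p of these genes was 1.22e-08, and each gene's CTL arrays lay wholly on one side of TUM (n = 3).

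All 31 adult contractile and fibre genes measured were higher in muscle, the same adjusted over the list alone, led by Ckmt2 (4.66 ± 0.17), Ampd1 (4.32 ± 0.16) and Tcap (3.84 ± 0.09). The median was 2.15 (adjusted p = 8.29e-12; adjusted p = 0.262 with an estimated correlation). Myh4 (2.15 ± 0.12) and Ckm (1.77 ± 0.10) were higher too. Among 19 early and embryonic muscle genes 7 were higher and 11 lower, the same adjusted over the list alone, and the list missed the threshold (median -1.91, adjusted p = 0.0659). Slow myosin Myh7 (3.08 ± 0.18) was higher, and cardiac troponin Tnnt2 (-3.15 ± 0.13), the fetal receptor subunit Chrng (-2.87 ± 0.15), Myh3 (-2.74 ± 0.12) and Myog (-2.40 ± 0.14) were lower. That list passed with arrays centred on their median (-1.77, adjusted p = 0.0188) or on their brightest genes (-1.67, 0.00738), a range of 0.000168 to 0.656 over all alternatives.

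All 31 cell cycle genes were lower in muscle, the same adjusted over the list alone, led by Top2a (-4.78 ± 0.22), Ccna2 (-4.42 ± 0.21) and Bub1 (-4.40 ± 0.26), with Mki67 (-3.70 ± 0.12) and Ccnd1 (-3.36 ± 0.09). The median was -2.96 (adjusted p = 5.79e-16; adjusted p = 0.197 with an estimated correlation). Of 24 YAP and TAZ target genes 16 were lower and 6 higher, the same adjusted over the list alone. Myof (-3.69 ± 0.10), Ankrd1 (-3.55 ± 0.16), Ajuba (-3.34 ± 0.12) and Dock5 (-2.65 ± 0.18) were lowest, Ccn1 (-1.78 ± 0.07) and Ccn2 (-0.82 ± 0.07) were lower too, and Amotl1 (1.63 ± 0.12) was higher. The median was -1.40 (adjusted p = 0.000235; adjusted p = 0.158 with an estimated correlation). Of 16 ribosome biogenesis and Myc genes 14 were lower and 1 higher, the same adjusted over the list alone, with Myc (-2.38 ± 0.12) and Nop58 (-2.33 ± 0.09) lowest and Mycn (0.85 ± 0.10) higher. The median was -0.79 (adjusted p = 3.1e-05; adjusted p = 0.262 with an estimated correlation). Yap1 differed by -0.29 ± 0.07 (adjusted p = 0.00283), a call lost under the 3 other scalings (-0.17, -0.16 and -0.05).

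All 20 oxidative phosphorylation and citrate cycle genes were higher in muscle, the same adjusted over the list alone, led by Ppargc1a (4.41 ± 0.15) and Cox7a1 (4.03 ± 0.07). The median was 1.34 (adjusted p = 2.55e-08; adjusted p = 0.174 with an estimated correlation). All 11 adipocyte markers were higher too, the same adjusted over the list alone, led by Retn (4.31 ± 0.12) and Plin4 (4.04 ± 0.14). The median was 2.57 (adjusted p = 2.72e-05; adjusted p = 0.197 with an estimated correlation). Of 15 endothelial markers 14 were higher and 1 lower, the same adjusted over the list alone, with Flt1 (1.84 ± 0.06) highest and Plvap (-0.61 ± 0.12) lower. The median was 1.00 (adjusted p = 0.000713; adjusted p = 0.262 with an estimated correlation).

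All 17 interferon response genes were lower in muscle, the same adjusted over the list alone, led by the chemokine Cxcl10 (-4.82 ± 0.25) and the regulator Irf7 (-4.00 ± 0.13). The median was -2.99 (adjusted p = 6.01e-12; adjusted p = 0.158 with an estimated correlation). Of 20 macrophage markers 19 were lower and 1 higher, the same adjusted over the list alone, with Msr1 (-3.94 ± 0.10) and Ctss (-3.90 ± 0.10) lowest and Cd163 (0.87 ± 0.19) higher. The median was -2.97 (adjusted p = 1.58e-10; adjusted p = 0.262 with an estimated correlation). Of 18 fibroblast and matrix genes 11 were lower and 4 higher, the same adjusted over the list alone, with Postn (-2.76 ± 0.10) and Col5a2 (-2.31 ± 0.11) lowest and Lum (1.46 ± 0.26) higher. The median was -0.98 (adjusted p = 0.0028; adjusted p = 0.378 with an estimated correlation). That call was lost among genes above the median level (adjusted p = 0.168; 1.43e-06 to 0.378 over all alternatives). All 4 sex-linked genes measured were lower, the same adjusted over the list alone: the Y-linked Uty (-2.70 ± 0.23), Eif2s3y (-2.43 ± 0.19) and Kdm5d (-0.99 ± 0.12) and the X-linked Xist (-0.37 ± 0.12). The median was -1.71 (adjusted p = 0.028; adjusted p = 0.317 with an estimated correlation). The Xist call was lost without CTL replicate 1 (-0.33, adjusted p = 0.057) and with 2 of the other scalings (-0.23 and -0.13). The sex-linked list call was lost among genes above the median level (median -0.37, adjusted p = 0.82; 4.92e-05 to 0.82 over all alternatives).

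The other lists did not pass. Genes higher and lower in muscle were 5 and 11 of 19 Hippo pathway components (median -0.41, adjusted p = 0.0861), 8 and 11 of 19 satellite cell and myoblast genes (median -0.72, adjusted p = 0.108), 5 and 5 of 14 p53 and apoptosis genes (median -0.07, adjusted p = 0.574), 4 and 6 of 13 oncofetal and imprinted genes (median -0.27, adjusted p = 0.108), and 9 and 3 of 14 hypoxia and glycolysis genes (median 0.63, adjusted p = 0.0789). They were 6 and 2 of 12 neutrophil markers (median 0.18, adjusted p = 0.78), 6 and 6 of 15 lymphocyte and NK markers (median 0.05, adjusted p = 0.574), 7 and 4 of 11 pericyte and smooth muscle markers (median 0.26, adjusted p = 0.51), 5 and 2 of 7 Schwann cell markers (median 0.52, adjusted p = 0.734), and 2 and 0 of 2 erythroid markers (median 1.04, adjusted p = 0.177). These counts were the same adjusted over the list alone. The neutrophil list's mean (-0.26) lay below 0 with median and test above, and the lymphocyte list's mean (-0.51) and test below with the median above. Within these lists, Vcam1 (-3.78 ± 0.11) and Myf5 (-3.45 ± 0.08), Hmga2 (-3.40 ± 0.06) and Mest (-2.90 ± 0.13) and Mdm2 (-2.43 ± 0.13) were lower in muscle, and Pfkfb3 (3.42 ± 0.13) and Hk2 (2.58 ± 0.08), Pax7 (0.38 ± 0.08) and the potassium channel gene Abcc9 (3.65 ± 0.11) were higher. The p53 list's median turned positive under the 3 other scalings (0.07 to 0.18), and the hypoxia list passed with quantile normalisation (adjusted p = 0.0465) and among genes above the median level (0.00699; 5.88e-08 to 0.303 over all alternatives). The satellite list passed with arrays centred on their brightest genes (-0.48, adjusted p = 0.0302; 3.27e-06 to 0.381 over all alternatives). Fry also called the Hippo, satellite cell, early muscle, p53, oncofetal, hypoxia, pericyte and erythroid lists. Myod1 was lower (-0.52 ± 0.17, adjusted p = 0.0162), a call lost with arrays centred on their median (-0.38) or brightest genes (-0.27).

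Over all genes 15199 passed, 9161 higher and 6038 lower in muscle, and 4451 by at least 2-fold (1724 and 2727). The groups did not overlap in 16494 genes (82.7%), where chance gives 10%. The median of all genes was 0.15 higher in muscle as deposited, 0.04 with quantile normalisation, 0.29 with arrays centred on their median and 0.39 on their brightest genes. The share of changed genes that were higher moved with it, from 60.3% as deposited to 54.6%, 69.3% and 72.7% (12783 higher and 4790 lower in the last case). Among genes above the median level the split turned, with 3373 higher and 5028 lower (40.1% higher), so it depends on the scaling and on the genes tested.

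Against TUM, 1746 genes were higher at both day 3 and day 6, where independent calls would give 396.8. Lower at both were 2383 (531.9), with 14 in opposite directions. Across genes, the log2 differences of the 2 days had a covariance of 0.153, against 0.00498 in simulated unchanged groups that share simulated TUM arrays, and a correlation of 0.853 against 0.496. For day 3 and control muscle, 1598 were higher in both (1227.3) and 2483 lower in both (968.2), with 925 opposite and a correlation of 0.499, the same as simulated (0.499), but a covariance of 0.214 against 0.00501. For day 6 and control muscle the counts were 2026 (1361), 2782 (1004.6) and 683, with a correlation of 0.557 against 0.496 and a covariance of 0.259 against 0.00499. The 3 TUM arrays cannot be divided into parts of at least 2 arrays, so some of the shared change can come from the shared controls. Genes are not independent replicates.

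**Figure D2:**
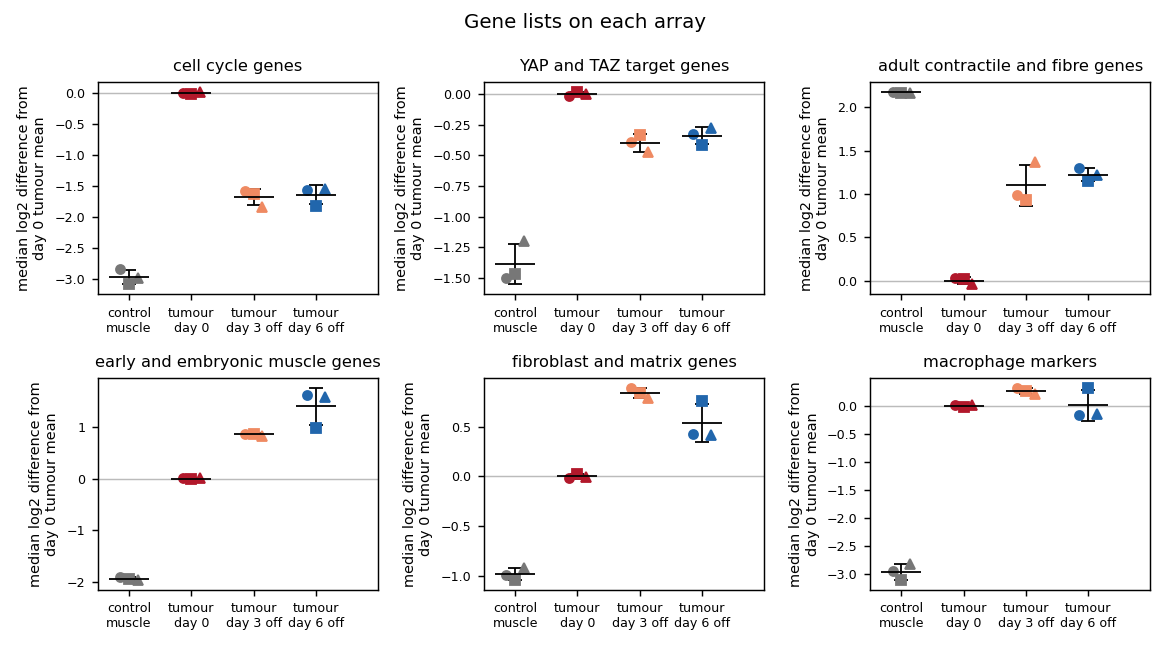
Median log2 difference of 6 gene lists from the mean of the day 0 tumours, on each array (circle, square and triangle are replicates 1, 2 and 3), with the group mean as a bar and the SD as whiskers (n = 3). The early and embryonic list lies at 0.83 to 0.87 on the day 3 arrays and at 1.63, 0.99 and 1.59 on day 6 replicates 1, 2 and 3.

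From day 3 to day 6 most early muscle genes rose further, and the fibroblast, endothelial and macrophage lists passed downwards, with falls in 8 of 18, 6 of 15 and 3 of 20 genes. With an estimated correlation these 3 lists did not pass (adjusted p = 0.197, 0.179 and 0.316), and fry did not call the macrophage list. Myh8 (1.40 ± 0.17) rose from a log2 intensity of 10.52 ± 0.12 to 11.92 ± 0.37 (SD, n = 3; adjusted p = 0.00117). Tcp11x2 (2.31 ± 0.27), Hephl1 (2.27 ± 0.33) and Atp1b4 (2.26 ± 0.16) rose most, Atp1b4 being a muscle protein, and Gzmf (-3.15 ± 0.31), Gzmd (-2.72 ± 0.25) and Gzmg (-2.27 ± 0.25) fell most. The largest adjusted p of these genes was 0.00242, and in each the OFF6 and OFF3 arrays did not overlap. In a model of only these 6 arrays 30 genes passed. Of the genes named here and below for this comparison, Myh8, Atp1b4, Gzmf and Gzmd were among the 30, and all others lost their call or had none.

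Of 19 early and embryonic muscle genes 14 rose and 0 fell, with 17 rises adjusted over the list alone and 17 without OFF6 replicate 2. Tnnt1 (1.02 ± 0.13), Myh7 (0.97 ± 0.18), Mybph (0.92 ± 0.14) and Myh3 (0.71 ± 0.12) rose beside Myh8, though none of these 4 passed in the model of only the 6 arrays (adjusted p from 0.0583 to 0.109). The median was 0.65 (adjusted p = 1.83e-12; adjusted p = 0.197 with an estimated correlation). Of 31 adult contractile and fibre genes 9 rose and 3 fell (12 and 5 adjusted over the list alone), and the list missed the threshold (median 0.12, adjusted p = 0.06), also without OFF6 replicate 2 (11 rises and 4 falls). Ldb3 (0.72 ± 0.13) rose and the fast-fibre myosin-binding Mybpc2 (-0.98 ± 0.15) fell. Pvalb (-1.84 ± 0.40) fell more, but its call was lost without OFF6 replicate 1 (-1.53, adjusted p = 0.0733) or replicate 3 (-1.52, 0.0792; 1.94e-07 to 0.129 over all alternatives). The contractile list passed without OFF3 replicate 3 (median 0.27, adjusted p = 1.27e-06), with quantile normalisation (0.0128), arrays centred on their brightest genes (0.0398), a trended and robust variance (0.0398), array weights (5.65e-05) and a replicate block (0.037), a range of 1.27e-06 to 0.717 over all alternatives. Of 20 oxidative phosphorylation and citrate cycle genes 4 rose and 0 fell, the same adjusted over the list alone and 9 rises without OFF6 replicate 2. The median was 0.11 (adjusted p = 0.00243; adjusted p = 0.3 with an estimated correlation). The median was 0.07 without OFF6 replicate 3 (adjusted p = 0.0102; 0.000175 to 0.3 over all alternatives).

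Of 18 fibroblast and matrix genes 8 fell and 0 rose, with 11 falls adjusted over the list alone, including Col6a1 (-0.55 ± 0.10) and Col6a3 (-0.51 ± 0.09). The median was -0.35 (adjusted p = 1.52e-08; adjusted p = 0.197 with an estimated correlation). Of 15 endothelial markers 6 fell and 0 rose, with 11 falls adjusted over the list alone, including the junction genes Cdh5 (-0.54 ± 0.07) and Cldn5 (-0.34 ± 0.06). The median was -0.25 (adjusted p = 5.75e-07; adjusted p = 0.179 with an estimated correlation). Of 20 macrophage markers 3 fell and 0 rose, with 5 falls adjusted over the list alone. The median was -0.28 (adjusted p = 8.77e-07; adjusted p = 0.316 with an estimated correlation). Leaving out OFF6 replicate 2, 14 fibroblast genes, 10 endothelial markers and 17 macrophage markers fell, with macrophage median -0.46. The fibroblast list then had 1 rise. The macrophage median was -0.18 without OFF6 replicate 1, and fry did not call the macrophage list (adjusted p = 0.0757; 2.77e-11 to 0.316 over all alternatives). Of 17 interferon response genes 3 rose and 0 fell, with 5 rises adjusted over the list alone, led by Usp18 (0.50 ± 0.08). The median was 0.20 (adjusted p = 0.00268; adjusted p = 0.262 with an estimated correlation). That call was lost without OFF6 replicate 2 (4 rises, median 0.14, adjusted p = 0.0511; 7.65e-05 to 0.262 over all alternatives).

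Of 19 satellite cell and myoblast genes 2 rose and 5 fell (3 and 9 adjusted over the list alone), with Megf10 (1.18 ± 0.20) up and Cxcr4 (-0.92 ± 0.16) down. The median was -0.24 (adjusted p = 0.0224; adjusted p = 0.262 with an estimated correlation). The call was lost without OFF6 replicate 2 (4 rises and 5 falls, median -0.13, adjusted p = 0.372), without OFF3 replicate 1 (-0.18, 0.0781), with quantile normalisation (0.0528), with array weights (0.155) and among genes above the median level (0.426), with a range of 0.00464 to 0.426 over all alternatives. Without OFF3 replicate 2 the median was -0.15 and the call was kept. Of 4 sex-linked genes 0 rose and 2 fell (0 and 3 adjusted over the list alone; median -0.57, adjusted p = 0.00455; adjusted p = 0.262 with an estimated correlation). That list had 3 falls without OFF6 replicate 2 (median -0.81, adjusted p = 0.000455) and did not pass among genes above the median level (0.63), a range of 0.000455 to 0.63 over all alternatives.

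The other lists did not pass. Rises and falls were 4 and 4 of 24 YAP and TAZ target genes (median 0.05, adjusted p = 0.831), with Ankrd1 (0.92 ± 0.16) and Gadd45a (0.68 ± 0.12) up, and 4 and 3 of 19 Hippo pathway components (median 0.06, adjusted p = 0.785), with Tead4 (1.27 ± 0.21) up. They were 1 and 0 of 31 cell cycle genes (median 0.06, adjusted p = 0.933), 3 and 2 of 14 p53 and apoptosis genes (median -0.01, adjusted p = 0.711), 2 and 2 of 13 oncofetal and imprinted genes (median -0.04, adjusted p = 0.443), 4 and 1 of 16 ribosome biogenesis and Myc genes (median 0.10, adjusted p = 0.143), and 1 and 0 of 14 hypoxia and glycolysis genes (median 0.13, adjusted p = 0.0664). They were 0 and 1 of 12 neutrophil (median 0.03, adjusted p = 0.838), 0 and 0 of 15 lymphocyte and NK (median 0.06, adjusted p = 0.838), 1 and 3 of 11 pericyte and smooth muscle (median -0.06, adjusted p = 0.209), 0 and 1 of 11 adipocyte (median 0.04, adjusted p = 0.439), 0 and 0 of 7 Schwann cell (median -0.01, adjusted p = 0.555) and 0 and 0 of 2 erythroid markers (median 0.10, adjusted p = 0.542). Adjusted over the list alone, counts were 7 and 7 for YAP and TAZ target, 4 and 5 for Hippo, 0 and 0 for cell cycle, 3 and 3 for p53, 3 and 2 for oncofetal, 5 and 2 for ribosome, 2 and 0 for hypoxia and 0 and 0 for neutrophil genes, and otherwise the same. Means below 0 with medians above 0 were seen for neutrophil, lymphocyte and adipocyte markers (-0.05, -0.05 and -0.08), and the YAP list's test pointed down with its median above 0. Without OFF3 replicate 3 the cell cycle list passed downwards (median -0.11, adjusted p = 0.00739) and the hypoxia list upwards (0.15, 0.0246), and without OFF3 replicate 1 the ribosome list passed upwards (0.16, 0.0147). The hypoxia list also passed upwards with quantile normalisation and with array weights. With OFF6 replicate 2 left out, rises and falls were 8 and 6 for YAP and TAZ target genes (median 0.02), 6 and 6 for Hippo genes (median 0.13), 2 and 2 for cell cycle genes, 3 and 3 for p53 genes (median 0.03), 3 and 5 for oncofetal genes (median -0.09), 5 and 1 for ribosome genes, 5 and 2 for hypoxia genes (median 0.20), 0 and 2 for neutrophil genes (median 0.00), 0 and 4 for lymphocyte genes (median -0.03), 1 and 3 for pericyte genes (median -0.02), 0 and 3 for adipocyte genes (median -0.12), 0 and 1 for Schwann cell genes (median -0.09) and 0 and 0 for erythroid genes (median 0.15). Fry also called the hypoxia and pericyte lists.

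Of the other genes named in each comparison, Ccn2 (0.33 ± 0.07) and Myod1 (0.65 ± 0.17) passed upwards and Ckm (-0.44 ± 0.10) downwards, each with a call lost when single arrays were left out. The Ccn2 call was lost without OFF3 replicate 2 (adjusted p = 0.0516), OFF6 replicate 1 (0.0539) or OFF6 replicate 3 (0.0633), and the Ckm call without OFF6 replicate 1 (0.08) or replicate 3 (0.0753). The Myod1 call was kept only without OFF6 replicate 2, and adjusted p was 0.071 to 0.164 without any 1 of the other OFF3 or OFF6 arrays. Yap1 (0.04 ± 0.07), Ccn1 (0.17 ± 0.07), Pax7 (-0.26 ± 0.08), Myf5 (-0.10 ± 0.08), Myog (0.20 ± 0.14), Myh4 (-0.15 ± 0.12), Mki67 (-0.12 ± 0.12) and Ccnd1 (-0.05 ± 0.09) did not pass (smallest adjusted p = 0.0642); Ccn1 passed without OFF6 replicate 2 (0.22, 0.0345) and with array weights, Pax7 with array weights or a replicate block, and Myog with array weights. The Ccn2, Myod1 and Ckm calls were also lost in a model of only the 6 arrays, and that of Myod1 with a replicate block.

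Over all genes 2080 passed, 1206 higher and 874 lower at day 6, and 108 by at least 2-fold (76 and 32). The arrays did not overlap in 4218 genes (21.2%), where chance gives 10%. Without OFF6 replicate 2 the count was 4874 (2401 higher and 2473 lower), of which 2064 were among the 2080 with the same direction. Replicates 1 and 3 differ little (SD 0.108, against 0.287 and 0.278 from replicate 2), which narrows the spread in that fit. Whether these were separate tumours was not given. Without 1 other OFF3 or OFF6 array the count was 452 to 1987. The split between higher and lower depends on the scaling and on single arrays. It was 1021 and 1025 with arrays centred on their median and 897 and 1090 without OFF3 replicate 3.

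Day 6 tumours were also compared with control muscle, to see how far they lay from it. They were higher in embryonic muscle, cell cycle, macrophage and interferon genes and lower in adult contractile, mitochondrial and fat genes. Of 19 early and embryonic muscle genes 15 were higher and 3 lower, the same adjusted over the list alone, with Myh3 (5.02 ± 0.12), Chrng (4.54 ± 0.15), Tnnt2 (4.20 ± 0.13) and Mymk (4.13 ± 0.15) highest and Myh7 (-1.54 ± 0.18) lower. The median was 2.63 (adjusted p = 1.36e-06; adjusted p = 0.3 with an estimated correlation). Of 31 adult contractile and fibre genes 30 were lower and 0 higher, the same adjusted over the list alone, led by Ckmt2 (-3.55 ± 0.17), Pvalb (-3.11 ± 0.40) and Mybpc2 (-2.94 ± 0.15). The median was -0.95 (adjusted p = 1.15e-08; adjusted p = 0.303 with an estimated correlation). Of 31 cell cycle genes 28 were higher and 2 lower, the same adjusted over the list alone, with Ccna2 (2.62 ± 0.21) and Top2a (2.56 ± 0.22) highest. The median was 1.42 (adjusted p = 9.93e-10; adjusted p = 0.262 with an estimated correlation). Of 24 YAP and TAZ target genes 15 were higher and 5 lower (16 and 5 adjusted over the list alone), with Ankrd1 (3.14 ± 0.16), Myof (2.84 ± 0.10) and Dock5 (2.72 ± 0.18) highest and Crim1 (-1.81 ± 0.15) lower. The median was 0.76 (adjusted p = 0.000666; adjusted p = 0.158 with an estimated correlation). When OFF6 replicate 2 was left out, genes higher and lower were 27 and 2 for cell cycle genes and 17 and 5 for YAP and TAZ target genes, and the other counts were the same.

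Of 17 interferon response genes 17 were higher, led by Cxcl10 (4.51 ± 0.25) and Irf7 (4.51 ± 0.13). The median was 3.21 (adjusted p = 1.79e-14; adjusted p = 0.158 with an estimated correlation). Of 20 macrophage markers 19 were higher and 1 lower, led by Ctss (4.17 ± 0.10) and Adgre1 (3.77 ± 0.16). The median was 2.82 (adjusted p = 1.29e-11; adjusted p = 0.262 with an estimated correlation). Of 18 fibroblast and matrix genes 15 were higher and 1 lower, led by Tnc (3.98 ± 0.15) and Postn (3.40 ± 0.10). The median was 1.04 (adjusted p = 1.99e-07; adjusted p = 0.219 with an estimated correlation). Of 16 ribosome biogenesis and Myc genes 11 were higher and 2 lower, with Nop58 (1.46 ± 0.09) highest. The median was 0.41 (adjusted p = 0.00686; adjusted p = 0.416 with an estimated correlation). All 20 oxidative phosphorylation and citrate cycle genes were lower, led by Ppargc1a (-3.50 ± 0.15). The median was -1.15 (adjusted p = 4.15e-09; adjusted p = 0.158 with an estimated correlation). Of 11 adipocyte markers 10 were lower, led by Retn (-4.18 ± 0.12). The median was -2.28 (adjusted p = 6.19e-06; adjusted p = 0.188 with an estimated correlation). Of 15 endothelial markers 12 were lower and 1 higher, with Flt1 (-1.79 ± 0.06) lowest. The median was -0.62 (adjusted p = 0.00404; adjusted p = 0.3 with an estimated correlation). Of 14 hypoxia and glycolysis genes 9 were lower and 2 higher, with Pfkfb3 (-2.90 ± 0.13) lowest. The median was -0.62 (adjusted p = 0.00554; adjusted p = 0.198 with an estimated correlation). Of 4 sex-linked genes 3 were higher and 0 lower. The median was 1.77 (adjusted p = 0.0224; adjusted p = 0.308 with an estimated correlation). These counts were the same adjusted over the list alone. Among genes above the median level the calls of the ribosome list (adjusted p = 0.0558; 0.000252 to 0.416 over all alternatives) and the sex-linked list (median 0.22, adjusted p = 0.871; 4.97e-05 to 0.871 over all alternatives) were lost. When OFF6 replicate 2 was left out, genes higher and lower were 15 and 2 for fibroblast genes, 12 and 2 for ribosome genes and 0 and 11 for adipocyte genes, and the other counts were the same.

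The other lists did not pass. Genes higher and lower were 10 and 5 of 19 Hippo pathway components (median 0.37, adjusted p = 0.178), 11 and 6 of 19 satellite cell and myoblast genes (median 0.37, adjusted p = 0.104), 6 and 3 of 14 p53 and apoptosis genes (median 0.29, adjusted p = 0.142), and 5 and 3 of 13 oncofetal and imprinted genes (median -0.07, adjusted p = 0.148). They were 2 and 3 of 12 neutrophil (median -0.05, adjusted p = 0.905), 7 and 4 of 15 lymphocyte and NK (median 0.09, adjusted p = 0.191), 3 and 6 of 11 pericyte and smooth muscle (median -0.35, adjusted p = 0.619), 2 and 4 of 7 Schwann cell (median -0.37, adjusted p = 0.739) and 0 and 2 of 2 erythroid markers (median -0.89, adjusted p = 0.161). These counts were the same adjusted over the list alone. The oncofetal and neutrophil lists had means (0.71 and 0.14) and tests above 0 with medians below. The satellite list passed with arrays centred on their brightest genes (0.11, adjusted p = 0.0225) or on their median (0.0328; 5.01e-05 to 0.378 over all alternatives). When OFF6 replicate 2 was left out, genes higher and lower were 10 and 6 for Hippo genes, 10 and 5 for satellite cell genes, 6 and 2 for p53 genes (median 0.08), 5 and 4 for oncofetal genes, 1 and 3 for neutrophil genes, 4 and 6 for pericyte genes and 1 and 5 for Schwann cell genes, with the other counts the same. Fry also called the Hippo, satellite cell, p53, oncofetal, lymphocyte, pericyte and erythroid lists. Of the genes named in each comparison, Ccn1 (0.48 ± 0.07) and Ccn2 (1.23 ± 0.07), Myf5 (2.56 ± 0.08), Myod1 (1.67 ± 0.17) and Myog (3.61 ± 0.14) and Mki67 (1.92 ± 0.12) and Ccnd1 (2.19 ± 0.09) were higher with a largest adjusted p of 4.73e-05. Pax7 (-0.69 ± 0.08), Myh4 (-1.12 ± 0.12) and Ckm (-1.20 ± 0.10) were lower (at most 1.01e-05), and Yap1 did not pass (0.05 ± 0.07, adjusted p = 0.583).

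Over all genes 12790 passed, 5602 higher and 7188 lower in the tumours, and 3420 by at least 2-fold (2124 and 1296). Without OFF6 replicate 2 the counts were 5627 and 6593, and 11637 genes were called in the same direction both ways. The groups did not overlap in 13655 genes (68.5%), where chance gives 10%. The median of all genes was -0.09 as deposited and between -0.35 and -0.04 under the 3 other scalings, and the share of changed genes that were higher was 43.8% as deposited, 44.6% with quantile normalisation, 27.2% with arrays centred on their median and 24.2% (4090 higher and 12830 lower) on their brightest genes. Among genes above the median level the split turned, with 4683 higher and 3240 lower (59.1% higher).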

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

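Tests chosen only after the result was seen were those of the scaling, of genes like the contractile ones, of muscle of one make-up, of a differentiation programme, of the muscle-gene position of OFF6 replicate 2, of gene sets inside the day 3 range and of other cell types in it; the muscle share, the position by all genes and the splits were planned.

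The changes against day 0 differed between day 6 and day 3 by a test of the difference itself in 2080 genes. The same test over lists gave medians of -0.243 for satellite cell and myoblast genes, 0.648 for early and embryonic muscle genes, 0.109 for oxidative phosphorylation and citrate cycle genes and 0.196 for interferon response genes. Medians were -0.278 for macrophage markers, -0.253 for endothelial markers, -0.352 for fibroblast and matrix genes and -0.57 for sex-linked genes. With an estimated correlation none of these 8 list calls was kept (adjusted p from 0.179 to 0.316). Leaving out OFF6 replicate 2 ended those of the satellite cell (median -0.131, adjusted p = 0.372) and interferon lists (0.143, 0.0511), and leaving out OFF3 replicate 1 that of the satellite cell list (0.0781). Fry did not call the macrophage list (0.0757). Over all alternatives adjusted p reached 0.426, 0.262 and 0.316 for the satellite cell, interferon and macrophage lists. For OFF6 minus OFF3, the 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05; the real one called 2080 genes and the highest other 481, with OFF3 replicates 1 and 2 and OFF6 replicate 2 on one side.

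In the other comparisons the splits are also too few for a share under 0.05, and 1 of the 10 splits, the real one, gave as many genes each time. Real counts were 5868 for OFF3 minus TUM, 6279 for OFF6 minus TUM, 15199 for CTL minus TUM and 12790 for OFF6 minus CTL, and limma called 0 genes in the highest other split of each.

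Adult contractile genes rose at day 3 and day 6, and muscle tissue of the host taken along with the regressing tumours could do the same. The scaling of the arrays is excluded as the whole cause, since the lowest list median under 3 other scalings was 1.091 at day 3 and 1.145 at day 6. The share of control muscle implied by 212 other genes at least 8-fold higher in muscle had a median of 5.33% at day 3 and 3.75% at day 6, against 32.7% and 37.3% for the contractile list and 19.6% and 22.1% for its 9 genes that are 8-fold higher. The implied share grew with the brightness of a gene, from 2.46% to 11.2% at day 3 and from 1.72% to 12.2% at day 6, so 24 of the 31 contractile genes were set beside other genes of like level and like difference from TUM. Their median share was 31% at day 3, against 12.3% for the like genes (quartiles 7.88% and 18.4%), and 41.4% at day 6, against 14.5% (8.64% and 27.8%). These shares assume that carried-over muscle has the profile of CTL, and host muscle beside a tumour was not measured. Muscle like CTL is therefore excluded as the whole cause at both days, and a smaller share of it stays open. Muscle of one make-up at both days would move all genes at least 8-fold higher in muscle one way, but 58 of 223 fell and 36 rose from day 3 to day 6. A model of only the 6 arrays called 6 and 1. With 1 array left out, falls ran from 23 to 77 and rises from 15 to 46. With no model, the OFF6 arrays lay wholly below OFF3 in 71 genes (31.8%) and wholly above in 37 (16.6%), where chance gives 5% each. Differences both ways argue against muscle of one make-up as the whole cause, but do not exclude it. The bound was set after the result was seen, and the model of only the 6 arrays would not show it alone. Genes that move together also make the 5% a loose guide. Changes in the tumour cells beside such muscle stay open. A differentiation programme in tumour cells may account for the 13 of 19 early and embryonic genes above both TUM and CTL at day 6 (0 of 31 contractile genes). Host muscle unlike CTL cannot be told apart from such a programme here.

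OFF6 replicate 2 lay apart from its group, and a day 3 sample under a day 6 name could explain it. Its position from OFF3 (0) to OFF6 replicates 1 and 3 (1) was 0.252 over all genes, outside the OFF3 arrays (0.028, 0.084 and 0.187) but by too little to decide alone. Over genes at least 8-fold higher in muscle it was 0.456, against 0.082, 0.122 and -0.048. Of 7 gene sets, 6 of them lists that differ between the days with and without this array, 5 lay outside the range of the OFF3 arrays. Early muscle genes (0.99 against 0.832 to 0.87), endothelial markers (0.408 against 0.537 to 0.549) and fibroblast genes (0.757 against 0.793 to 0.896) lay outside it towards OFF6 replicates 1 and 3. Mitochondrial genes (0.155 against 0.099 to 0.153) lay just outside it that way, and macrophage markers (0.317 against 0.209 to 0.308) outside it on the far side from replicates 1 and 3 (-0.165 and -0.146). The 2 sets inside share their genes: Y-linked genes lay at 0.611 (0.519 to 0.859, with replicates 1 and 3 at -0.253 and -0.246). The interferon and satellite cell lists were not used, since their calls between the days were lost without this array (adjusted p = 0.0511 and 0.372). A 4th array of one group lies outside the range of 3 in 1 of 2 cases by chance. The test over all genes did not reach its bound, which was set before it was run. A day 3 sample therefore cannot be told apart. A higher share of all other cell types alike was not seen in every marker set. Macrophage markers lay 0.54 above replicates 1 and 3 (lower quartile 0.309), and pericyte markers did not (-0.014, upper quartile 0.099). This rests on the pericyte markers, and which marker sets to use was changed after their values were seen. Such a share is therefore not excluded. The spreads of macrophage, fibroblast (0.249) and endothelial markers (0.175) overlap, and more macrophages or more of these 3 types stays open. A slower regression of this tumour is open and was not tested.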

How the results depend on the processing

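The alternatives added after results were seen leave out OFF6 replicate 2 from list tests and from counts of shared genes. Gene results left as they were numbered 389 with array weights, 425 with a replicate block, 431 to 436 under the 3 other scalings and 439 or 440 with another probe set choice or variance. They numbered 377, with 63 calls lost, in models of only the 6 arrays. Of the 110 list results, 58 were left as they were with an estimated correlation and 77 with fry; the choice of probe set changed none of the list calls, and the 3 other scalings kept 100 to 104. For the following, the cause was not tested unless named.

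Array weights called 11175 genes for OFF3 minus TUM (6181 higher), 10545 for OFF6 minus TUM (5658 higher) and 8424 for OFF6 minus OFF3 (4120 higher), so most changes against TUM were then rises. They ran from 0.16 for OFF6 replicate 2 to 6.42 for OFF3 replicate 2, and turned Xist in OFF3 minus TUM (-0.177) and Uty (-0.293) and Eif2s3y (-0.253) in OFF6 minus TUM. A minimum of 2-fold left, by construction, 760, 892, 4451, 108 and 3420 genes in OFF3, OFF6 and CTL minus TUM, OFF6 minus OFF3 and OFF6 minus CTL. Testing fewer genes, those above the median level, gave 8401 for CTL minus TUM (3373 higher and 5028 lower) and 7923 for OFF6 minus CTL (4683 and 3240), turning both splits, and testing all probe sets gave 23072 for CTL minus TUM. For OFF6 minus OFF3, an adjusted p under 0.01 left 467 genes and a model of only the 6 arrays 30. Leaving out 1 array gave 452 to 4874 there (without OFF6 replicate 3 and 2), 4541 to 5829 for OFF3 and 4856 to 6886 for OFF6 minus TUM, 13613 to 14717 for CTL minus TUM and 11471 to 12300 for OFF6 minus CTL.

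With an estimated correlation, adjusted p was 0.158, 0.158 and 0.158 for YAP and TAZ targets (medians -0.381, -0.41 and -1.399 in OFF3, OFF6 and CTL minus TUM), 0.193, 0.197 and 0.262 for contractile genes (1.124, 1.187 and 2.148), and 0.158, 0.158 and 0.197 for cell cycle genes (-1.726, -1.655 and -2.961). Fry turned the oncofetal list of OFF6 minus TUM (median 0.186, adjusted p = 0.00831). The cell cycle list of OFF6 minus OFF3 ran from -0.108 without OFF3 replicate 3 to 0.165 without OFF3 replicate 1.

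A block for the replicate number gave 5476, 5891, 14821, 1654 and 12279 genes. Deviations of arrays with the same number correlated at -0.387 to 0.249, above 0.1 in 3 of 18 pairs, so the numbers do not pair the samples. The erythroid list held no genes above the median level, so that filter gave no value for it. A filter on probe set name endings was not run, since the names are plain numbers, and the ratio of 3' to 5' control probes was not analysed here. The number of arrays limits the precision.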

Other observations

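The osteoclast set and its tests, the granzyme genes, the test of all macrophages and that of cells of both sexes were chosen only after the result was seen; the test of X-linked partners was planned.

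Osteoclast genes fell after doxycycline removal. Atp6v0d2, Oscar, Mmp9 and Calcr prompted a set of 12 other osteoclast genes, of which 6 fell and 1 rose at day 3, with median -0.333 (camera p = 7.09e-06, 0.0146 with an estimated correlation). At day 6, 9 fell and 0 rose, with median -0.545 (6.55e-08 and 0.00577). These p-values are not adjusted, so they cannot be set beside the adjusted ones of the lists. Unadjusted, the cell cycle list at day 3 had camera p = 0.00989 with an estimated correlation. Ocstamp (-2.39 ± 0.11), Slc9b2 (-2.31 ± 0.08), Dcstamp (-1.62 ± 0.09), Ctsk (-1.65 ± 0.19) and Acp5 (-1.01 ± 0.13) fell most at day 6, with fusion receptors and bone-degrading enzymes among them. The macrophage markers argue against a fall of all macrophages as the whole cause at day 6. Their median was -0.025 (lower quartile -0.315), above the set's upper quartile of -0.25. Such a fall is not excluded, since the quartile ranges overlap and the bound was set after the values were seen. Leaving out OFF6 replicate 2, the macrophage list passed downwards (8 fell and 0 rose, adjusted p = 0.00154), with median -0.147 (lower quartile -0.541) against the set's median of -0.675 and upper quartile of -0.334, so a part of the fall may be shared by all macrophages. Osteoclast-type cells, or such genes in other cells, may have become fewer or less active.

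Some granzyme genes and the perforin gene Prf1 were lower at day 3 and day 6. Gzmf, Gzmd and Gzmg, among the 6 largest falls at day 6, drew attention to this family, so no test of it as a set is given. The differences from TUM were Gzmf (-1.09 ± 0.31), Gzmd (-1.25 ± 0.25), Gzmg (-1.39 ± 0.25), Gzme (-1.39 ± 0.26), Prf1 (-1.44 ± 0.12) and Gzmc (-0.70 ± 0.23) at day 3 and Gzmf (-4.24 ± 0.31), Gzmd (-3.97 ± 0.25), Gzmg (-3.66 ± 0.25), Gzme (-2.43 ± 0.26), Prf1 (-1.69 ± 0.12) and Gzmc (-1.42 ± 0.23) at day 6, all with an adjusted p under 0.05. Gzmn (-0.02 ± 0.06) did not pass at day 3 (adjusted p = 0.82), nor at day 6 (-0.03, adjusted p = 0.683), and related granzymes can share probes. No explanation was tested.

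Y-linked transcripts were higher in the tumours than in control muscle, with a median difference TUM minus CTL of 2.431 over 3 genes. This is a lower bound, since Uty and Eif2s3y in control muscle (log2 4.56 to 4.84) lay below the lower quartile of the arrays. Signal from their X-linked partners is excluded as the whole cause, since these differed by a median of 0.052, far below that bound and below the 0.99 of Kdm5d, which lay above that quartile. Xist was 0.373 higher in TUM than in CTL, so cells of both sexes may be present in the tumours, such as donor cells of one sex in a host of the other; the sexes were not given in the sources used here.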
